A study of Mus musculus with 72 samples.

How the data were processed

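The data are RNA sequencing of mouse liver from 72 libraries, 1 per animal. Per the labels, mice of 2 strains, C57BL/6J and DBA/2J, and of both sexes were fed a Control, Medium Protein or Low Protein diet from 10 weeks of age for 13 weeks. They were killed at 23 weeks after a 16 h fast and were housed at about 22 °C. Strain, sex and diet give 12 groups of 6 animals. Codes in the labels that read like positions run in the order of these groups. An effect that follows this order therefore cannot be fully told apart from strain, sex or diet. Row letters of these codes recur across groups, and no fit with position was run. A further strain named in the series title was not analysed here. Stranded libraries of polyadenylated RNA were spread over 2 lanes, and the reads of both lanes were merged before quantification, per the labels.

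The submitters' processing notes name RSEM, edgeR, limma and R 3.4.3. The aligner, the genome build, the annotation and the versions of RSEM, edgeR and limma are not given in the sources used here. The deposited count table holds RSEM expected counts per gene, 1 column per library, for 51912 genes named by Ensembl identifiers without coordinates. Of its values, 11.6% were not whole numbers, and they were rounded before the fit. A table by the authors holds a log2 fold change, a p-value and an adjusted p-value per gene and diet comparison for 17575 genes, and the authors' F statistic, a score per gene that was not used. Gene symbols came from the GENCODE M21 names, which matched 51633 identifiers and left 279 without a name.

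Total counts per library ran from 26.9 to 38.4 M, with a median of 32.4 M. Genes were kept by the filterByExpr function of edgeR with the 12 groups, which left 19362 genes tested. Libraries were scaled by TMM. Levels are given as CPM after TMM scaling, with the standard deviation (SD) over the 6 animals of a group, or over the 36 libraries of a strain in the check of strain labels. Intervals and lower bounds on a fold cover counting error only, and a lower bound takes 3 counts over the 6 libraries of the group at 0.

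All 72 libraries entered a single edgeR 4.0.16 quasi-likelihood fit of the 12 group means in R 4.3.3. The common biological coefficient of variation was 0.207. Low Protein and Medium Protein were compared with Control, and Low Protein with Medium Protein, in each of the 4 combinations of strain and sex. The mean effect of each diet over the 4 combinations was also tested. Interaction contrasts tested whether the Low Protein effect differed between the sexes of a strain (male minus female) or between the strains of a sex (DBA/2J minus C57BL/6J). On the Control diet, males were compared with females and DBA/2J with C57BL/6J. This gave 22 comparisons. Tests of genes and gene lists were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Adjusted p-values of genes below are from this edgeR fit, and the error of a log2 fold change is its standard error (SE).

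For 34 gene lists of liver pathways and cell types, camera from limma 3.58.1 was run with a preset correlation of 0.01, adjusted over the lists of a comparison. Alternatives were camera with an estimated correlation and fry. A list needed 4 tested members, so pancreatic acinar and skeletal muscle markers were counted but not tested, which left 32 lists. Calls of members were counted over all genes tested and also adjusted over the list alone. The same gene can be in several lists, and markers of a cell type can also be expressed by hepatocytes. Overlaps of calls between the 4 Low Protein comparisons, which share no animals, were tested by one-sided Fisher's exact test for an excess over chance. Adjustment was over all pairs and directions. Overlaps between the Low Protein and Medium Protein effects were not tested, because both use the same Control animals.

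The comparisons, the gene lists, the main alternatives and the rule for named genes were set before the data were examined. The rule takes called genes with a mean log2 CPM of at least 0 and leaves out predicted or unnamed genes. It names the 12 highest and 12 lowest fold changes with 1 sign in all 4 combinations for the mean Low Protein effect. For single combinations it takes 6 and 6 for Low Protein against Control, 4 and 4 for Medium Protein against Control, and 2 and 2 for Low against Medium Protein. It takes the 6 smallest p for an interaction, 8 and 8 for sex and strain, and per list up to 4 called members and 2 others. Fgf21, Igf1, Igfbp1, Cyp7a1, Asns and the genes of the label checks are always named. Genes shown for sharing calls between combinations were chosen after their values were seen. Mup, Serpina1, Cyp2c, Cyp3a41, Sult2a, Hba, Hbb, Gstp and immunoglobulin genes have near-identical copies, so reads may be divided between copies and a value for 1 of them is less certain.

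Alternatives were RLE factors, library totals, leaving out the 10 most abundant genes, no filter, a filter of 1 CPM in 6 libraries, limma-voom, DESeq2 1.42.0, a test against a fold of 1.2, a fit of the compared groups only, the letter of the animal code as a covariate, and keeping 1 animal of each pair that shares a number. Removals of single libraries, and of 4 libraries with a high share of 3 genes resembling ribosomal RNA (AY036118, CT010467.1 and Lars2, over 5% of counts), were added after seeing the data. For each comparison, other splits of the same libraries were refitted. There were 100 splits per comparison, and 50 for each mean effect, the real split included. The edgeR fit and camera were tested on simulated data, for Low Protein against Control in males only. Other comparisons, the interactions, the overlaps and the splits were not simulated. In C57BL/6J males on Low Protein, 100 genes were changed 1.5-fold and 100 were changed 2-fold, with as many lowered as raised. Of these, 72 and 87 were recovered, and 12 of 171 calls were false. With no simulated effect in DBA/2J males, 0 genes were called and 0 of 32 lists passed. Simulated genes varied independently of each other, so this cannot show how often lists of correlated genes pass camera by chance. Outlying libraries and differences between strains or sexes were not simulated, so the share of 12 in 171 need not hold for the real data. Files were read with the data.table package, version 1.17.8, and plots used Python 3.11.15 and matplotlib 3.10.9.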

Results

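The series asks how diets lower in protein act on metabolism in mice of different strain and sex, here read from liver RNA. Each of the 12 groups of strain, sex and diet held 6 animals. Library totals lay between 26.9 and 38.4 M counts. Of all counts, mt-Rnr2, a mitochondrial ribosomal RNA, took 15.3%, and Alb, the gene of serum albumin, took 4.89%.

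The expression of sex-linked and strain-dependent genes went with the labels. Xist, the RNA that silences an X chromosome in females, stood at 1095 to 1996 CPM in female libraries and at no more than 2.29 CPM in males. Ddx3y, Eif2s3y, Kdm5d and Uty, genes of the Y chromosome, were highest in males. Their lowest male values were 60.3, 17.7, 20.8 and 23.0 CPM, and their highest female values were 2.74, 0.821, 0.667 and 0.744 CPM. Hc, which encodes complement C5, stood at 815 ± 222 CPM (SD over the 36 libraries of a strain) in C57BL/6J and 272 ± 44.3 CPM in DBA/2J. Glo1 averaged 166 ± 33.1 and 380 ± 92.1 CPM, and Alad 69.9 ± 11.5 and 157 ± 33.1 CPM, in the same order. For these 3 genes the ranges of the strains did not overlap, while those of Nnt and Gpnmb did. No library went against its label for sex (0 of 72).

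**Figure D1:**
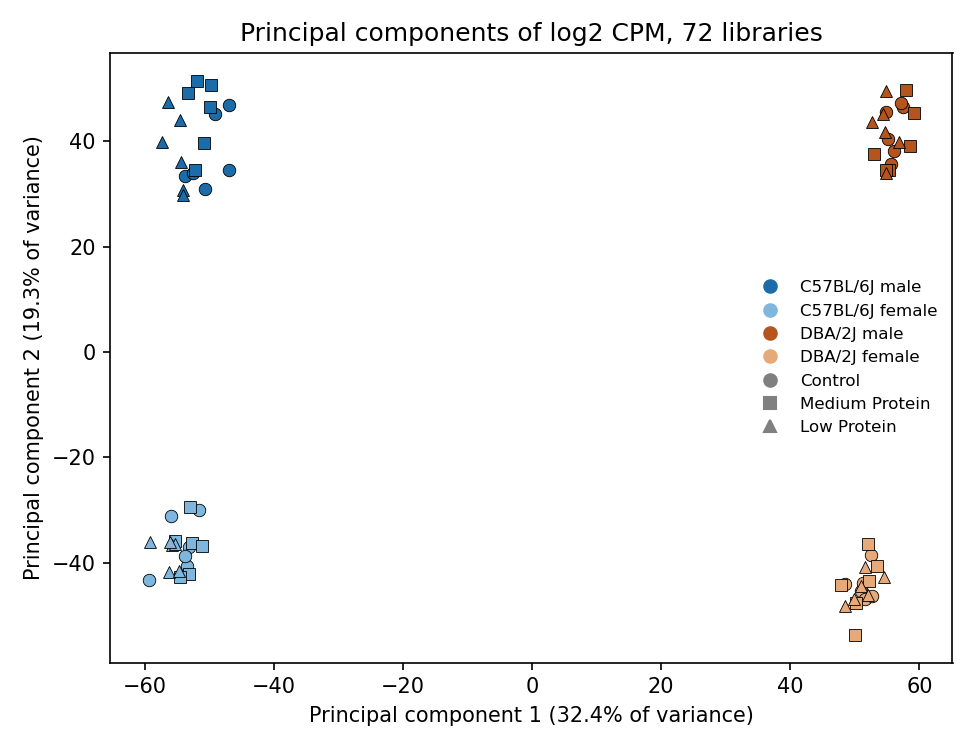
Scores of the 72 libraries on the first component (x axis, 32.4% of the variance) and the second (y axis, 19.3%) of log2 CPM, with strain, sex and diet marked per point. DBA/2J libraries score 47.8 or more on the first component and C57BL/6J libraries -46.9 or less, while males score 29.8 or more on the second and females -29.5 or less.

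In C57BL/6J males, Low Protein feeding came with higher Asns, Pdk4, Fgf21 and Lepr. Asns (ENSMUSG00000029752), which makes asparagine, rose from 1.26 ± 0.929 CPM on Control to 17.1 ± 6.14 CPM on Low Protein (SD, n = 6 each). Pdk4 (ENSMUSG00000019577), a kinase that holds back pyruvate oxidation, rose from 6.13 ± 1.76 to 78.6 ± 70.4 CPM. Fgf21 (ENSMUSG00000030827), a liver hormone induced by protein restriction, rose from 4.66 ± 1.13 to 18.6 ± 13.9 CPM. Lepr, the leptin receptor, rose from 18.3 ± 6.71 to 149 ± 49.8 CPM, and Hamp2, a hepcidin gene, fell from 4.07 ± 1.93 to 0.216 ± 0.144 CPM.

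On the log2 scale the changes were 3.76 ± 0.60 (SE) for Asns (adjusted p = 9.11e-06), 3.67 ± 0.52 for Pdk4 (8.87e-07) and 2.00 ± 0.41 for Fgf21 (0.000557). Lepr rose by 3.03 ± 0.44 (1.81e-06), Btbd19 by 2.86 ± 0.52 (8.76e-05), and Ppp1r3g, a subunit that directs a phosphatase to glycogen, by 3.05 ± 0.88 (0.0165). These 6 genes were above the Control median in 6 of 6 Low Protein libraries, and Gadd45b (2.53 ± 0.49, adjusted p = 0.000229) in 5 of 6. The lowest fold changes were Hamp2 (-4.18 ± 0.62, 2.42e-06), Cyp2b10 (-3.60 ± 1.10, 0.0245), Acpp (-3.46 ± 0.34, 1.83e-11), Dct (-3.44 ± 0.50, 1.61e-06), Lrtm1 (-3.37 ± 0.43, 7.26e-08) and Fam83f (-2.59 ± 0.49, 0.000135), each below the Control median in 6 of 6 libraries. With limma-voom Hamp2 (-4.39, 0.0822), Cyp2b10 (-2.92, 0.374), Ppp1r3g (2.79, 0.0788) and Gadd45b (1.73, 0.0515) did not pass, nor did Hamp2 (0.0728), Cyp2b10 (0.354) and Ppp1r3g (0.0732) in the authors' deposited table. Cyp2b10 (0.0737) and Ppp1r3g (0.0518) also missed the threshold against a fold of 1.2. Igf1 (-0.17, adjusted p = 0.358), Igfbp1 (1.31 ± 0.60, 0.166) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-0.84, 0.251), did not pass. In total 1894 genes passed, 790 higher and 1104 lower, and 325 of them changed at least 2-fold. With library totals in place of TMM the median of all genes shifted by 0.246 (log2) in this comparison, 5652 genes passed and 94.4% of them were higher, against 41.7% here. Without the 4 libraries with much ribosomal-like RNA, 1574 genes passed, 1385 of them shared with the 1894.

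**Figure D2:**
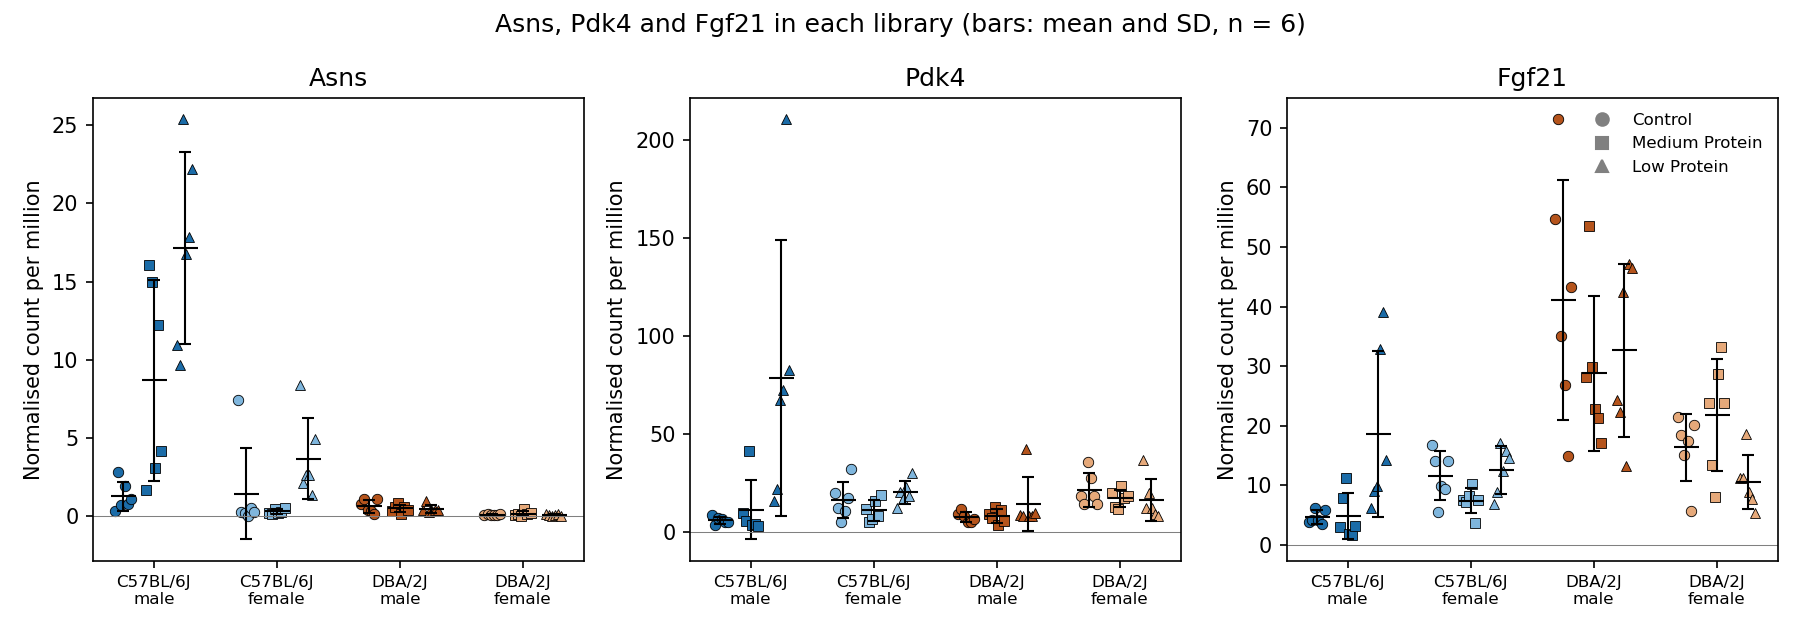
Asns, Pdk4 and Fgf21 in TMM-scaled CPM (y axis) in each library by strain, sex and diet (x axis), with bars for the mean and SD of 6 animals. Asns averages 1.26, 8.69 and 17.1 CPM on Control, Medium Protein and Low Protein in C57BL/6J males.

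Amino acid catabolism was the list with the most genes lower in C57BL/6J males. Of 52 amino acid catabolism genes 38 fell and 1 rose (45 and 2 adjusted over the list alone), with a median log2 change of -0.51. Examples are Asrgl1 (-0.79, adjusted p = 4.46e-08), Ftcd of histidine breakdown (-0.95, 1.2e-07), Agxt2 (-0.83, 1.72e-07) and Mccc2 of leucine breakdown (-0.46, 4.53e-06). The list passed camera at 1.79e-35, and its adjusted p = 0.00109 with an estimated correlation. Of 9 urea cycle genes 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.51. Otc fell from 223 ± 28.7 to 143 ± 17.2 CPM, Ass1 from 1463 ± 218 to 723 ± 126 CPM and Asl from 450 ± 116 to 220 ± 52.5 CPM, while Arg1 stood at -0.41 (adjusted p = 0.121). The urea cycle list passed at 1.99e-06, with an adjusted p = 0.0362 with an estimated correlation. Both medians remained below 0 with library totals, at -0.26 each.

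Serine, glycine and one-carbon genes went both ways, with 4 of 28 higher and 13 lower (6 and 15 alone, that is adjusted over the list alone). Psat1, an enzyme of serine synthesis, rose by 4.09 (adjusted p = 8.65e-07) and Aldh1l2, a mitochondrial folate enzyme, by 3.16 (3.33e-07). Gnmt, which uses up methyl groups, fell by 1.23 on the log2 scale (4.47e-07) and Dmgdh fell by 1.06 on the log2 scale (1.63e-09). The list's adjusted p was 1.72e-05, and adjusted p = 0.0561 with an estimated correlation. Its median was -0.27 and its mean -0.03. Among 34 targets of ATF4, the transcription factor of the amino acid stress response, 6 rose and 0 fell (10 and 0 adjusted over the list alone). The ATF4 list passed at 0.000632, with an adjusted p = 0.236 with an estimated correlation.

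In C57BL/6J males the lists of lipid, bile acid and detoxification genes included called genes. Of 40 fatty acid oxidation and PPARA targets 11 rose and 1 fell, among them Acot2 (1.71, adjusted p = 1.52e-05) and Cyp4a31 (1.81, 1.88e-05), and the list passed at 5.7e-09 (adjusted p = 0.236 with an estimated correlation). Of 27 bile acid genes 1 rose and 6 fell, among them Slc27a5 (-0.65, 3.29e-06) and Baat (-0.61, 2.57e-05), both of bile acid conjugation. The bile acid list passed at 6e-05 with adjusted p = 0.0362 with an estimated correlation, though its median turned from -0.20 to 0.05 with library totals. Of 25 cholesterol synthesis genes 0 rose and 3 fell, with Tm7sf2 at -0.99 (8.54e-05), at a list p of 9.55e-05 (adjusted p = 0.545 with an estimated correlation). Among 34 xenobiotic genes 3 rose and 9 fell, with Ugt1a9 at 1.65 (7.18e-06) and Gstm2 at -0.89 (0.000284), at a list p of 0.0014 (adjusted p = 0.405 with an estimated correlation).

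Interferon response genes fell in 14 of 32 cases and rose in 0 (22 and 0 adjusted over the list alone), with Oasl1 at -1.47 (6.01e-07) and Ifit1 at -1.20 (0.000867), and the list passed at 3.52e-12 (adjusted p = 0.215 with an estimated correlation). Heat shock genes rose in 9 of 18 cases, with Hspb1 at 2.46 (0.000113) and Hsp90aa1 at 1.28 (0.00196), at a list p of 2.41e-08 (adjusted p = 0.236 with an estimated correlation). Of 22 endoplasmic reticulum stress genes 4 rose and 0 fell (1.05e-05, adjusted p = 0.405 with an estimated correlation). Of 75 cytosolic ribosomal protein genes 23 rose and 0 fell, with Rpl5 at 0.36 (0.00018), at 2.26e-10 (adjusted p = 0.405 with an estimated correlation). Of 73 respiratory chain genes 0 rose and 18 fell, with Sdha at -0.47 (5.45e-06) and Sdhb at -0.57 (0.000282), at 8.33e-15 (adjusted p = 0.236 with an estimated correlation). The respiratory chain median turned from -0.19 to 0.05 with library totals. Red blood cell markers rose in 6 of 9 cases, with the globin gene Hbb-bs at 1.30 (0.000704), a median of 1.16 and a list p of 6.68e-06 (adjusted p = 0.194 with an estimated correlation).

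Of the 34 lists, 14 passed camera in C57BL/6J males, 3 of them with an estimated correlation. The others did not pass. Higher and lower members numbered 2 and 4 of 16 for gluconeogenesis (camera adjusted p = 0.271), 0 and 3 of 16 for glycolysis (0.0977), 2 and 2 of 30 for fatty acid synthesis (0.579), 2 and 1 of 29 for NRF2 targets (0.189) and 0 and 2 of 18 for the growth hormone and IGF1 axis (0.763). For male-biased genes they were 1 and 6 of 37 (0.752), for female-biased genes 4 and 6 of 43 (0.671), for acute phase genes 1 and 2 of 34 (0.172), for the circadian clock 1 and 1 of 21 (0.597) and for the cell cycle 2 and 0 of 26 (0.0807). Among cell types, macrophage markers had 1 and 0 of 21 (0.0574), cholangiocyte markers 1 and 1 of 13 (0.364), collagen and matrix markers 0 and 0 of 22 (0.752) and endothelial markers 0 and 0 of 18 (0.597). T and NK cell markers (19, 0.271), B and plasma cell markers (15, 0.23), neutrophil markers (4, 0.825) and adipocyte markers (6, 0.23) had 0 calls each, as did the 3 pancreatic acinar markers and the 1 skeletal muscle marker, which were too few to test.

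In C57BL/6J females, Low Protein feeding came with lower Sult1e1 and higher Elovl3. Sult1e1, which inactivates oestrogen, fell from 7.47 ± 5.68 to 0.304 ± 0.325 CPM (-4.60 ± 0.84, adjusted p = 0.000492). Cyp3a41b (-3.32 ± 0.64, 0.00128), Cyp3a16 (-2.05 ± 0.42, 0.00209) and A1bg (-2.10 ± 0.51, 0.00945) fell in 6 of 6 libraries. In a fit of the compared groups only these 3 did not pass (0.134, 0.225 and 0.102, at -3.32, -2.06 and -2.10), nor did Cyp3a16 with limma-voom (-1.72, 0.0554) or A1bg against a fold of 1.2 (0.0681). Elovl3, a fatty acid elongase that is male-biased in liver, rose from 1.22 ± 0.806 to 8.72 ± 2.52 CPM (2.83 ± 0.46, 7.5e-05), and Corin rose by 1.70 ± 0.28 (9.43e-05). Cyp3a11, a main drug-metabolising enzyme, rose by 1.12 ± 0.23 (0.00169).

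In all, 629 genes passed, 284 higher and 345 lower, of which 93 changed at least 2-fold. With library totals 295 passed, and in a fit of the compared groups only 87. Further named genes were Trim34b (1.68 ± 0.51, adjusted p = 0.0469), Trhde (-2.38 ± 0.64, 0.0232) and Mup2 (-1.92 ± 0.55, 0.0362). Without Low Protein replicate 1 these did not pass, at 1.41 (adjusted p = 0.137), -2.08 (0.0574) and -1.91 (0.0548). By contrast, that library carried Orm2 (3.83 ± 0.90, 0.00759, higher in 1 of 6 libraries), Cxcl13 (2.73 ± 0.71, 0.0186) and Isyna1 (1.39 ± 0.35, 0.0146), which stood at -1.06, -0.24 and 0.11 without it. Fgf21 (0.12), Igf1 (-0.24, adjusted p = 0.21) and Cyp7a1 (0.79, 0.376) did not pass, though Igf1 did without Low Protein replicate 1 (-0.35, 0.0418). Asns stood at 1.36 ± 0.56 (0.183), and without Control replicate 1, which had 7.43 CPM, it rose by 3.95 (1.91e-05). With all libraries, limma-voom called Asns at 3.35, and the authors' deposited table gives 3.35 (0.0112). Of 43 female-biased genes 5 fell and 0 rose (7 and 0 adjusted over the list alone, list adjusted p = 0.000389), and of 73 respiratory chain genes 7 rose and 0 fell (1.1e-12). Both calls were lost at adjusted p = 0.854 with an estimated correlation. Interferon (0.000389), PPARA targets (0.00144), ribosomal proteins (0.000219), the clock (0.00821) and cholesterol synthesis (0.0105) also passed camera, and their adjusted p lay between 0.854 and 0.953 with an estimated correlation. Without Control replicate 1, ribosomal proteins (0.0907) and PPARA targets (0.339) did not pass.

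In DBA/2J males few genes changed. Meg3, a long non-coding RNA, fell from 5.02 ± 2.47 to 1.04 ± 0.732 CPM (-2.27 ± 0.43, adjusted p = 0.00908, lower in 6 of 6 libraries). Nt5e, which makes adenosine outside the cell, fell by 0.76 on the log2 scale (SE 0.15, 0.00908), and so did Antxr2 (-0.65 ± 0.13, 0.00908), Ddx52 (-0.37 ± 0.08, 0.0144) and Arl1 (-0.32 ± 0.07, 0.0141). Gal3st1 and Galc, enzymes that make and break down galactolipids, rose by 2.38 ± 0.54 (0.0418) and 0.49 ± 0.10 (0.0144). Asns (-0.42), Pdk4 (0.90) and Fgf21 (-0.33) did not pass.

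There were 18 calls, 9 higher and 9 lower, 6 of them at least 2-fold. Aatk (0.97 ± 0.21, adjusted p = 0.0236), Chsy1 (0.45 ± 0.10, 0.0418), Scpep1 (0.41 ± 0.08, 0.0144) and Lpp (0.28 ± 0.06, 0.0418) were the other named genes that rose. Without Control replicate 4, which had 10.0% ribosomal-like RNA, 9 genes passed, 1 higher and 8 lower. Mup12 (-6.01 ± 0.92, 0.000254), a urinary protein gene with near-identical copies, then stood at -0.25, while Gal3st1 (2.26, 0.131), Aatk (0.98, 0.0648), Galc (0.48, 0.0634), Chsy1 (0.44, 0.128), Scpep1 (0.39, 0.0668) and Lpp (0.25, 0.16) had about the same fold change but did not pass. In a fit of the compared groups only, 0 genes passed. With library totals Antxr2 (-0.57, 0.0753), Arl1 (-0.25, 0.272) and Ddx52 (-0.29, 0.209) did not pass. Cholesterol synthesis genes had 0 calls over all genes and 11 higher of 25 adjusted over the list alone (median 0.60, list adjusted p = 3.45e-21), with Dhcr7 at 0.72 (0.072) and Srebf2 at 0.52 (0.143). The adjusted p was 0.196 with an estimated correlation, as for fatty acid synthesis (median 0.23, 5.24e-06, adjusted p = 0.196 with an estimated correlation). Camera passed 11 lists in all, 0 with an estimated correlation.

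In DBA/2J females, several urea cycle genes rose on Low Protein. Arg1, the last enzyme of the urea cycle, rose from 640 ± 99.2 to 1093 ± 333 CPM (0.77 ± 0.17, adjusted p = 0.00927). Cps1, its first enzyme, rose by 0.72 ± 0.18 (0.0259) and Asl by 0.93 ± 0.24 (0.044). Cyp3a11 rose from 615 ± 108 to 1547 ± 390 CPM (1.33 ± 0.23, 0.000351), and Serpina12, the adipokine vaspin, from 7.76 ± 3.18 to 28.1 ± 12.9 CPM (1.85 ± 0.38, 0.00461). Osgin1 (-1.74 ± 0.37, 0.00572) and Snhg11 (-2.41 ± 0.49, 0.00459) fell in 6 of 6 libraries, though Snhg11 did not pass with limma-voom (-2.46, 0.11).

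Of 9 urea cycle genes 5 rose and 0 fell (median 0.43, list adjusted p = 1.2e-06), and of 16 glycolysis genes 5 rose and 0 fell (9 and 1 adjusted over the list alone, median 0.26, 4.27e-08), with Pgk1 at 0.45 (0.000265) and Gapdh at 0.37 (0.00871). Both kept an adjusted p = 0.0391 with an estimated correlation. Respiratory chain genes rose in 11 of 73 cases (38 higher and 1 lower adjusted over the list alone), with Atp5g1 at 0.42 (0.000257), and xenobiotic genes in 3 of 34, with Ces2a at 0.77 (0.000265). These lists passed at 4.4e-28 and 2.44e-08, and their adjusted p was 0.115 with an estimated correlation. Camera passed 14 lists, 2 with an estimated correlation.

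There were 158 calls in DBA/2J females, 118 higher and 40 lower, 37 of them at least 2-fold. Library totals left 69 with 56.5% higher, against 74.7% here, and 81 passed without Control replicate 2 and 96 without Low Protein replicate 3. Hist1h4h (-2.36, adjusted p = 0.028) and Hist1h4c (-2.24, 0.0259) stood at -1.30 (0.416) and -0.72 (0.699) without Control replicate 2, Hist1h4d (-1.83, 0.0281) had an adjusted p = 0.417, and Dpm3 (-1.37, adjusted p = 0.0285) at -1.09 (0.184). Olfr1033 (adjusted p = 0.0402) had 0 counts in all Control libraries and only 0.0849 ± 0.146 CPM (SD) on Low Protein. The lower bound of 6.15-fold leaves out the spread between animals, and with limma-voom the gene did not pass (1.85, 0.552). Tmc5 stood at 1.23 ± 0.33 (0.0484) and Pp2d1 at 1.10 ± 0.23 (0.00577). Without Low Protein replicate 3, Olfr1033 (0.276), Tmc5 (1.25, 0.069), Dpm3 (-1.34, 0.0676) and Gpc1 (1.25 ± 0.29, adjusted p = 0.0152, then 1.16, 0.0562) did not pass. The histone genes Hist1h4h (-2.37, 0.0633), Hist1h4c (-2.22, 0.0638) and Hist1h4d (-1.86, 0.0588) did not either, at about the same fold change. Olfr1033 (0.0978) and Tmc5 (1.23, 0.114) also missed the threshold without Control replicate 2.

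**Figure D3:**
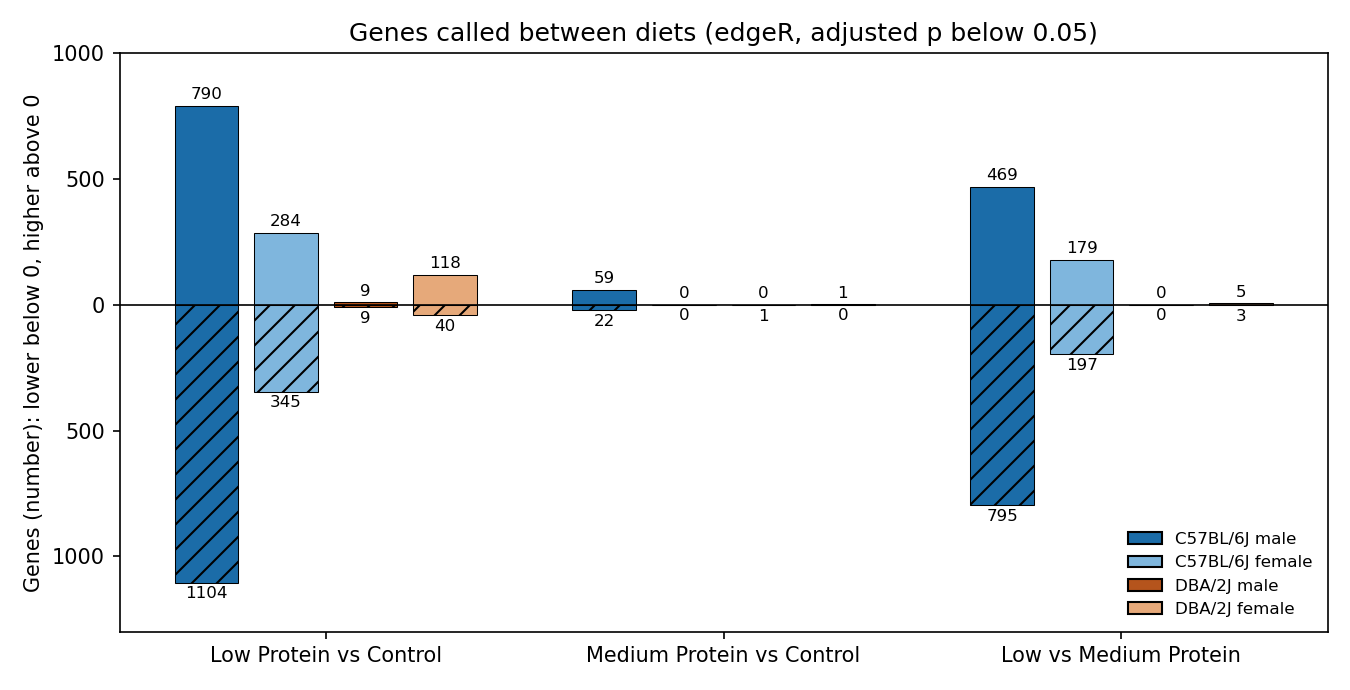
Number of genes called at an adjusted p below 0.05 (y axis) for each diet comparison (x axis), higher and lower apart, in the 4 combinations of strain and sex. Low Protein against Control gave 1894 genes in C57BL/6J males, 629 in C57BL/6J females, 18 in DBA/2J males and 158 in DBA/2J females.

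Tests of the difference showed that the Low Protein response of many genes depended on sex in C57BL/6J and on strain in males. Pdk4 rose more in C57BL/6J males than in females (difference 3.36, adjusted p = 0.00226) and more in C57BL/6J than in DBA/2J males (DBA/2J minus C57BL/6J -2.78, 0.0147). Lepr differed by sex and by strain (1.96, 0.039 and -2.30, 0.0227), and so did Hamp2 (-3.34, 0.00546 and 4.54, 0.00013). Fgf21 differed by strain (-2.33, 0.0105) and by sex (1.88, 0.0411), the latter with adjusted p = 0.0643 without C57BL/6J female Control replicate 1, 0.0628 without Low Protein replicate 1 of that strain and sex, and 0.0635 without the 4 libraries with much ribosomal-like RNA. Asns differed by strain (-4.18, 0.00551). Its difference by sex was 2.40 (0.0664), but -0.19 (0.926) without C57BL/6J female Control replicate 1 and 2.84 (0.028) without C57BL/6J female Low Protein replicate 1, so it is left open. With library totals the sex difference of Asns passed (2.66). With limma-voom, Hamp2 and Fgf21 passed for neither difference, and Lepr did not pass for sex (1.85). Elovl3 rose more in C57BL/6J females than in males (-2.76, 0.00307).

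By sex, 882 genes differed in C57BL/6J, 358 with a higher and 524 with a lower effect in males, and the smallest p belonged to Sulf2 (-2.23 ± 0.27, adjusted p = 2.63e-07), Acpp (-3.21 ± 0.44, 5.05e-06), Smim19 (-1.07 ± 0.16, 1.75e-05), Pex16 (-0.79 ± 0.12, 2.43e-05), P2ry4 (-1.19 ± 0.18, 3.45e-05) and App (0.88 ± 0.14, 9.22e-05). By strain in males, 558 differed, 382 with a higher and 176 with a lower effect in DBA/2J, led by P2ry4 (1.52 ± 0.18, 7.82e-08), App (-1.10 ± 0.14, 4.47e-07), Sulf2 (1.86 ± 0.27, 1.82e-05), Tmem63a (0.84 ± 0.12, 1.82e-05), Lrtm1 (3.84 ± 0.58, 1.97e-05) and Dmgdh (1.11 ± 0.17, 1.97e-05). In females 18 genes differed by strain, among them Prkar2a (0.48 ± 0.07, 9.44e-05), Slc10a2, the ileal-type bile acid transporter (2.41 ± 0.43, 0.00446), Man2a1 (0.61 ± 0.11, 0.0054), Slc27a1 (-1.39 ± 0.26, 0.0054), Cfap54 (-1.77 ± 0.34, 0.0057) and Smo (-0.94 ± 0.18, 0.00738). With library totals Prkar2a (0.44, 0.065) and Man2a1 (0.57, 0.0531) did not pass. In females the count was 83 without C57BL/6J female Control replicate 1. For sex in DBA/2J, edgeR called 0 genes, with 1478 at an unadjusted p below 0.05, while limma-voom called 0 and DESeq2 13. With library totals the median of all genes shifted by 0.237 for sex in C57BL/6J, 0.107 for sex in DBA/2J and -0.169 for strain in males. The share with a higher effect then became 94.8% in place of 40.6% for sex in C57BL/6J, 10.8% in place of 68.5% for strain in males and 16.7% in place of 33.3% for strain in females.

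With an estimated correlation, amino acid catabolism was the list that differed by both tests. For sex in C57BL/6J, 18 members had a lower effect in males and 0 a higher one (33 and 1 adjusted over the list alone), with an adjusted p = 0.0476 with an estimated correlation. For strain in males, 17 had a higher effect in DBA/2J and 0 a lower one (36 and 0 adjusted over the list alone), with an adjusted p = 0.012 with an estimated correlation. Hal, which starts histidine breakdown, differed by sex (-1.44, adjusted p = 0.00307) and Haao by strain (0.87, 0.000567). The urea cycle list differed by strain in males, with 3 members higher in DBA/2J (adjusted p = 0.0195 with an estimated correlation), and by sex its adjusted p = 0.184 with an estimated correlation. Of the 12 genes named for Low Protein in C57BL/6J males, 8 differed by sex and 8 by strain. For those named in C57BL/6J females the counts were 3 and 1 of 12, for DBA/2J males 0 and 4 of 12, and for DBA/2J females 0 and 0 of 12.

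**Figure D4:**
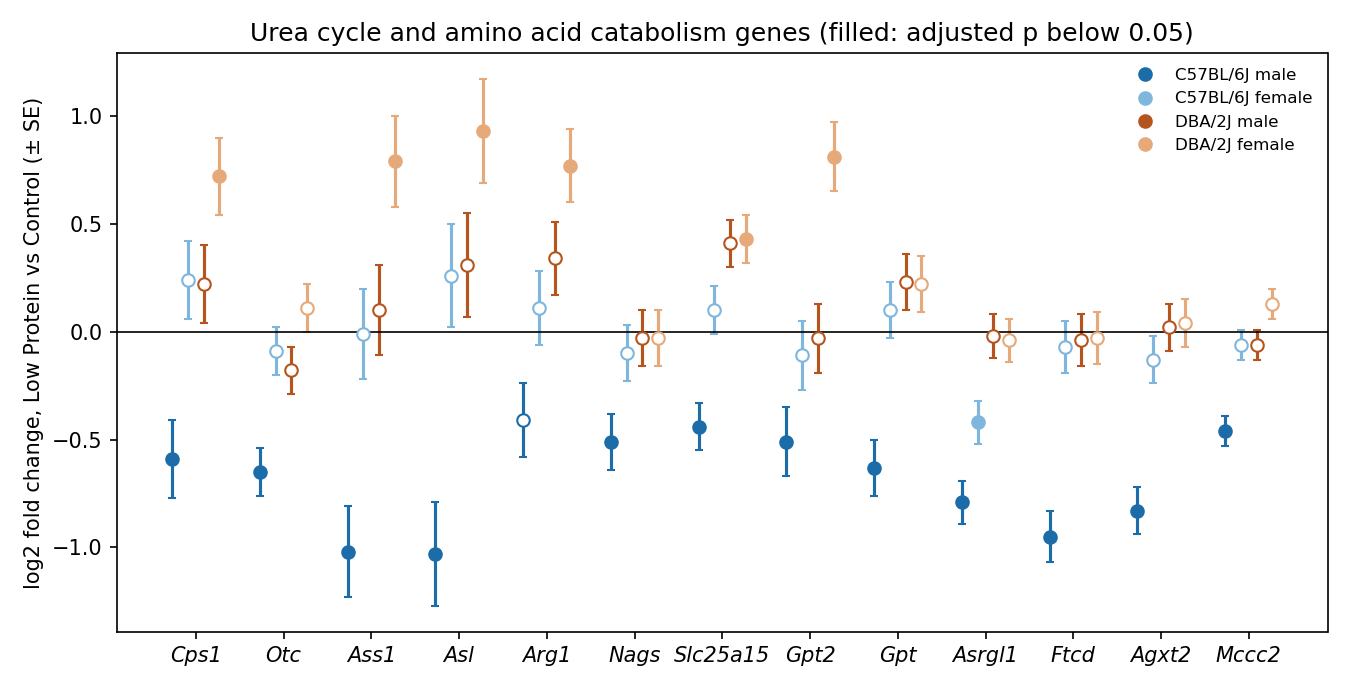
Log2 fold changes, Low Protein against Control (y axis), of urea cycle and amino acid catabolism genes (x axis) in the 4 combinations of strain and sex, with bars for the SE and filled points at an adjusted p below 0.05. Asl stands at -1.03 in C57BL/6J males and 0.93 in DBA/2J females.

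Some genes answered Low Protein alike in both sexes of C57BL/6J. Calls of the males and females had 131 genes in common with the same direction, out of 148 called in both. There were 50 higher genes, against 11.6 by chance (one-sided Fisher's exact test, adjusted p = 8.58e-18), and 81 lower, against 19.7 (1.73e-27). The test takes genes as independent, which they are not. Across all genes with a mean log2 CPM of at least 0, fold changes of the sexes of C57BL/6J correlated at only r = 0.07. Those of C57BL/6J males and DBA/2J females correlated at r = -0.029. C57BL/6J and DBA/2J females had 11 higher genes in common against 1.73 by chance (5.32e-06, Fisher's exact test), but among calls at an adjusted p below 0.01 only 2, against 0.252 (0.106). Between C57BL/6J males and DBA/2J females 31 genes were called in both and 23 went opposite ways, among them Asl (-1.03 and 0.93), Ass1 (-1.02 and 0.79), Cps1 (-0.59 and 0.72), Gpt2 (-0.51 and 0.81), Mdh1 (-0.41 and 0.42) and mt-Atp6 (-0.81 and 0.92). Ctps, Prkar2a and Zfp445 were called in 3 combinations and 0 genes in all 4. Prkar2a went opposite ways in C57BL/6J males (-0.16) and DBA/2J females (0.22), while Ctps (0.79 and 0.65) and Zfp445 (0.42 and 0.62) rose in both.

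Averaged over the 4 combinations, Low Protein came with higher Lepr (1.33 ± 0.21, adjusted p = 1.3e-05), Cyp3a11 (0.86 ± 0.11, 1.75e-07), Cidec, a lipid droplet protein (1.07 ± 0.23, 0.00137), and Elovl3 (1.04 ± 0.20, 0.000325). The phosphate transporter Slc34a2 (1.51 ± 0.31, 0.000683), Adgrg2 (1.13 ± 0.14, 8.7e-08) and Dynll1 (0.92 ± 0.09, 1.65e-11) rose too. Sult1e1 (-2.72 ± 0.47, 7.79e-05), the metallothioneins Mt1 (-1.21 ± 0.27, 0.00161) and Mt2 (-1.05 ± 0.32, 0.0312), and Clic5 (-0.87 ± 0.11, 6.04e-08) fell. The rule named only genes with the same sign in all 4 combinations, so that agreement is not a result. The size of the effect was not shared by all groups. Elovl3 rose less in C57BL/6J males than in females (male minus female -2.76). Lepr rose more in C57BL/6J males than in females (1.96) and than in DBA/2J males (DBA/2J minus C57BL/6J -2.30). The mean effect passed for 1551 genes, 743 higher and 808 lower, and with library totals 90.5% of 2419 were higher, against 47.9% here. Mt2 (-0.95, 0.0533) and Ppp1r3g (1.32 ± 0.43, 0.0421, then 1.26, 0.0536) missed the threshold without C57BL/6J female Control replicate 1, and Ppp1r3g (1.29, 0.0565) also without DBA/2J male Control replicate 4. Camera passed 10 lists, 0 of them with an estimated correlation (adjusted p from 0.494 to 0.654), with 12 of 32 interferon genes and 13 of 52 amino acid catabolism genes lower and 26 of 75 ribosomal protein genes higher.

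Medium Protein changed few genes. In C57BL/6J males Asns rose to 8.69 ± 6.44 CPM (2.78 ± 0.59, adjusted p = 0.0113, but 0.054 without the 4 libraries with much ribosomal-like RNA), and male-biased Selenbp2 (2.45 ± 0.48, 0.00708) and Scara5, a ferritin receptor (2.91 ± 0.57, 0.00773), rose as well. Rtn4rl1 fell by 0.91 on the log2 scale (SE 0.15, 0.0012). In DBA/2J males the single call was Mup12 (-5.85 ± 0.92, 0.000397), which stood at -0.10 without Control replicate 4, leaving 0 calls. In DBA/2J females the single call was Fcgbp (3.35), outside the rule for named genes and given after its value was seen, and 0 genes passed without Medium Protein replicate 6 or without Control replicate 2.

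In C57BL/6J males 81 genes passed, 59 higher and 22 lower. Without the 4 libraries with much ribosomal-like RNA 82 passed, 41 higher and 41 lower, 37 of them shared with the 81. Further named genes were Moxd1 (5.68 ± 1.40, adjusted p = 0.0447), Cyp2b9 (-2.62 ± 0.65, 0.0424), Vldlr (-1.64 ± 0.41, 0.0447), Ube2d2b (-0.74 ± 0.18, 0.0424), Igdcc4 (4.13 ± 1.02, 0.0427) and Sult1e1 (3.97 ± 0.82, 0.0101). Igdcc4 was -0.11 without Medium Protein replicate 2, and Sult1e1 was 0.13 without Medium Protein replicate 5, which left 48 genes. Without replicate 5 Scara5 (2.23, 0.06), Moxd1 (5.08, 0.103), Cyp2b9 (-2.36, 0.105), Vldlr (-1.46, 0.128) and Ube2d2b (-0.68, 0.108) did not pass, nor did Moxd1 (5.39, 0.0589), Cyp2b9 (-2.41, 0.0765) and Vldlr (-1.61, 0.066) without replicate 2. In a fit of the compared groups only 0 genes passed, and with library totals 91.0% of 111 were higher, against 72.8% here. In C57BL/6J females edgeR called 0 genes, with 1465 at an unadjusted p below 0.05, limma-voom 0 and DESeq2 10. For the mean effect edgeR called 0, with 1040 at an unadjusted p below 0.05, limma-voom 0 and DESeq2 7. The Medium Protein comparisons gave 14, 11, 7, 7 and 10 list calls in C57BL/6J males, C57BL/6J females, DBA/2J males, DBA/2J females and their mean, and 0 with an estimated correlation. Without C57BL/6J female Control replicate 1, most list calls in C57BL/6J females and several for the mean were lost. In these females the camera adjusted p of the cell cycle list went from 0.00245 to 0.521, and that of ATF4 targets from 0.0258 to 0.792. Of 37 male-biased genes 5 rose in C57BL/6J males (12 adjusted over the list alone, median 0.48), with an adjusted p = 0.333 with an estimated correlation.

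Between the lower-protein diets, C57BL/6J males on Low Protein had more Pdk4 (2.78 ± 0.50, adjusted p = 8.94e-05), Pcp4l1 (2.84 ± 0.35, 4.21e-08) and Fgf21 (1.95, 0.00101) and less Igf1 (-0.36, 0.0236) than males on Medium Protein. Without Medium Protein replicate 5, Igf1 did not pass (-0.33, 0.0697), nor did it with library totals (-0.18). In a fit of the compared groups only Pdk4 (2.80, 0.0628) and Fgf21 (1.96) did not pass. Amino acid catabolism genes were lower in 36 of 52 cases and higher in 1, interferon genes lower in 19 of 32, urea cycle genes in 5 of 9 and bile acid genes in 4 of 27. With an estimated correlation these lists had adjusted p = 0.00113, 0.0387, 0.0387 and 0.0474. Mt1 (-3.41, 3.6e-05) and Mt2 (-3.81, 0.000264) were lower. In C57BL/6J females Asns was higher on Low Protein (3.64, 0.00077), and Cyp3a41b (-3.86 ± 0.65, 0.000313) was lower.

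The counts were 1264 in C57BL/6J males (469 higher, 795 lower), 376 in C57BL/6J females (179 and 197) and 8 in DBA/2J females (5 and 3). In DBA/2J males edgeR called 0 genes, with 1103 at an unadjusted p below 0.05, limma-voom 0 and DESeq2 7. Sult1e1 in males (-6.35 ± 1.02, adjusted p = 1.09e-05) was -2.51 (0.117) without Medium Protein replicate 5, and Tff3 (-4.09 ± 0.97, 0.00366) was -2.25 (0.163) without replicate 2. In females Orm2 (4.87), Igdcc4 (3.95) and Mup15 (-2.97, 0.0263) were -0.03, 0.35 and -2.78 (0.0644) without Low Protein replicate 1. In DBA/2J females Zfand4 (0.83 ± 0.16, 0.0142), Cyp3a13 (0.76 ± 0.16, 0.0482) and Mtmr10 (-0.34 ± 0.07, 0.0374) were named. There 3 genes passed without Low Protein replicate 3 and 3 without Medium Protein replicate 6. Cyp3a13 (0.81 and 0.74, adjusted p = 0.0531 and 0.0884) and Mtmr10 (-0.36 and -0.35, 0.0531 and 0.0503) then missed the threshold at about the same fold change. Library totals shifted the median of all genes by 0.186 in C57BL/6J males and gave 90.8% higher, against 37.1%, with 67.6% against 47.6% in C57BL/6J females and 33.3% against 62.5% in DBA/2J females. In DBA/2J males, cholesterol synthesis had 0 calls over all genes and 19 higher of 25 adjusted over the list alone (median 0.68, 3.38e-28, adjusted p = 0.0573 with an estimated correlation). Camera passed 14, 7, 12 and 16 lists in C57BL/6J males, C57BL/6J females, DBA/2J males and DBA/2J females, and 4, 0, 0 and 0 with an estimated correlation.

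On the Control diet, large differences between the sexes included genes of the Cyp3a, Sult and Mup families and of the Y chromosome. In C57BL/6J, Cyp3a41a averaged 1181 ± 657 CPM in females and 0.242 CPM in males, and Sult2a1, a steroid sulfotransferase, 224 ± 133 CPM in females with 3 counts in all 6 males. Mup7, a urinary protein gene, averaged 6013 ± 3052 CPM in males and 2.96 ± 2.67 CPM in females. In DBA/2J, Sult3a1 averaged 1054 ± 200 CPM in females and 0.0945 CPM in males, and Cyp4a12a, which hydroxylates fatty acids, 359 ± 22.2 CPM in males and 0.171 CPM in females. Ddx3y was at least 5139-fold higher in C57BL/6J males and at least 6758-fold in DBA/2J males than in females of the strain, where it had 0 counts.

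Other genes higher in C57BL/6J males included Hsd3b5 (10.54), Cyp4a12a (9.65), Uty (9.02) and Eif2s3y, at least 2271-fold. AY036118 (10.70) and CT010467.1 (9.42), which collect reads like ribosomal RNA, had adjusted p = 0.0629 and 0.0699 without the 4 libraries rich in such reads, at 4.91 and 3.82. Cyp3a41b was at least 4431-fold and Sult2a3 at least 1126-fold lower in C57BL/6J males, and Xist stood at -11.11. With limma-voom, AY036118 (0.0525), Cyp3a41b (0.109) and Sult2a3 (0.262) did not pass in C57BL/6J. In DBA/2J males Cyp4a12b (11.45), Uty (10.25), Mup15 (9.85) and Mup7 (9.60) were higher, with Eif2s3y at least 3068-fold and Moxd1 at least 1217-fold, of which Mup15 (0.0639) and Moxd1 (0.266) did not pass with limma-voom. Sult2a5 was at least 1039-fold and Sult2a6 at least 635-fold lower there, with Sult3a2 at -12.86, Cyp3a16 at -12.41, Sult2a1 at -12.30, Cyp3a41b at -11.59 and Cyp3a41a at -11.35. In total 4021 genes differed in C57BL/6J (2243 higher and 1778 lower in males) and 3539 in DBA/2J (2019 and 1520). Library totals shifted the median of all genes by -0.336 and -0.282, and the share higher in males became 5.32% in place of 55.8% in C57BL/6J and 7.59% in place of 57.05% in DBA/2J.

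The lists of sex-biased genes went the way of their names. Of 37 male-biased genes 31 were higher and 1 lower in C57BL/6J males (adjusted p = 4.49e-08 with an estimated correlation) and 33 and 1 in DBA/2J males (1.95e-09). Of 43 female-biased genes 37 were lower in males of each strain (adjusted p = 3.11e-07 and 1.95e-09 with an estimated correlation). Cholesterol synthesis genes were higher in 24 of 25 cases in C57BL/6J males (median 1.31, adjusted p = 0.0946 with an estimated correlation), with Mvk at 1.64 (2.16e-07) and Srebf2 at 0.96 (1.73e-07). In DBA/2J Srebf2 was lower in males (-0.59, 0.001). Endoplasmic reticulum stress genes were higher in 18 of 22 cases in DBA/2J males (median 0.73, adjusted p = 0.486 with an estimated correlation), with Fkbp11 at 1.42 (1.01e-07). Camera passed 14 lists in C57BL/6J and 9 in DBA/2J, 2 in each with an estimated correlation.

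Between strains on Control, Xaf1 and Gvin1 were among the genes that differed. Xaf1 averaged 26.5 ± 2.53 CPM in DBA/2J males and 4.40 ± 0.509 CPM in C57BL/6J males (2.59, adjusted p = 6.04e-22). Gvin1, a large interferon-induced GTPase, had 0 counts in DBA/2J and was at least 3094-fold lower in males and 3171-fold in females. Serpina3c averaged 238 ± 22.9 CPM in DBA/2J males and 0.992 CPM in C57BL/6J males, and C1s2, a complement protease gene, 37.6 ± 3.50 and 0.138 CPM. In females, Mup1 averaged 711 ± 403 CPM in DBA/2J and 2.58 CPM in C57BL/6J, and Cyp2a22 151 CPM in C57BL/6J with 3 counts in all 6 DBA/2J libraries. Fgf21 was higher in DBA/2J males (3.14, 1.06e-08), at 41.1 ± 20.2 CPM.

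Interferon genes were higher in DBA/2J in 27 of 32 cases in males (median 1.05) and in 26, with 1 lower, in females (median 0.81), and the lists had adjusted p = 0.53 and 0.644 with an estimated correlation. Cholesterol synthesis genes were lower in DBA/2J males in 12 of 25 cases (adjusted p = 0.8 with an estimated correlation) and higher in DBA/2J females in 17 (median 0.71, adjusted p = 0.644 with an estimated correlation). Higher in DBA/2J males were also Obp2a (8.25), Ifi202b (8.11), Ctse (7.35) and Nuggc (7.09), and lower Cyp2a22 (-7.23), Acpp (-6.94), Olfr1034 (-6.74), Trim12a (-6.67) and CT868723.1 (-6.27). In DBA/2J females Ctse (7.35), Sult2a6 (7.09) and Serpina3c (10.33) were higher, with Obp2a at least 726-fold and Ifi202b at least 554-fold. Lower there were CT868723.1 (-7.17), Mup15 (-7.08) and Zfp125 (-6.78), with Olfr1033 at least 734-fold and Trim80 at least 244-fold. Mup15 did not pass there with limma-voom (0.134). In all 5905 genes differed in males (2889 higher and 3016 lower in DBA/2J) and 5385 in females (2666 and 2719). Library totals shifted the median of all genes by 0.105 in males and gave 67.0% higher, against 48.9%. Camera passed 11 lists in males and 12 in females, 0 in each with an estimated correlation. A strain's sequence can differ from the reference, which limits values of single genes between strains.

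The authors' deposited table called 1924, 732, 24 and 188 genes for Low Protein against Control in C57BL/6J males, C57BL/6J females, DBA/2J males and DBA/2J females. Of these, 1738, 569, 16 and 134 were also called here. For Medium Protein the authors' deposited table called 40 genes in C57BL/6J males, 39 of them called here, and 0 in the other groups. For Low against Medium Protein the authors' deposited table called 1225, 423, 0 and 24 genes, of which 1119, 335, 0 and 7 were also called here. Fold changes correlated across genes, which are not independent replicates, at r from 0.79 to 0.893.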

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

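Tests chosen only after the result was seen were, for the call difference between strains, the removal of libraries rich in ribosomal-like RNA, for the male transcripts, Xist and the C57BL/6J share, and for the amino acid genes, the scaling, the hepatocyte share and the removal of the same libraries.

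The response to Low Protein differed between groups by the test of the difference itself. By sex in C57BL/6J 882 genes differed, by strain in males 558 and by strain in females 18. The genes with the smallest p by sex were Sulf2 (-2.23), Acpp (-3.21), Smim19 (-1.07), Pex16 (-0.79), P2ry4 (-1.19) and App (0.88), each as male minus female. By strain in males they were P2ry4 (1.52), App (-1.10), Sulf2 (1.86), Tmem63a (0.84), Lrtm1 (3.84) and Dmgdh (1.11), and by strain in females Prkar2a (0.48), Slc10a2 (2.41), Man2a1 (0.61), Slc27a1 (-1.39), Cfap54 (-1.77) and Smo (-0.94), each as DBA/2J minus C57BL/6J.

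More genes were called on Low Protein in C57BL/6J males (1894) than in DBA/2J males (18). Libraries rich in ribosomal-like RNA are argued against, since 443 genes still differed by strain in males without the 4 of them. Depth is argued against, since 1884 genes were called in C57BL/6J males and 2 in DBA/2J males with the male libraries thinned to 28.5 M counts each, against 1912 and 1 in the same fit before thinning. A larger spread in DBA/2J is argued against by a median SE 0.970 times that in C57BL/6J, in fits of each strain alone. The response itself differed between the strains by the test above (558 genes), and a biological cause may underlie it, as a hypothesis, with causes such as food intake untested.

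A DBA/2J female library, Medium Protein replicate 6, held low levels of male transcripts. A male animal labelled female is argued against by Xist at 1666 CPM, within the female range of 1095 to 1996. A small share of DBA/2J male liver RNA or library could account for it, as 6 transcripts had a median of 2.55% of the DBA/2J male level. Against this, Mup15, 1 of the 6, was at 0 CPM against 147 CPM in males. The next highest of 18 female libraries had 0.0259%, but the transcripts were chosen as near 0 in the other females, which keeps that value low. A share from C57BL/6J males is argued against by -0.0691% over 11 transcripts that DBA/2J animals lack. Where such RNA entered stays open, and no biological explanation was tested.

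Amino acid catabolism and urea cycle genes were lower on Low Protein in C57BL/6J males. Scaling moves all genes of a library alike and is argued against, since the urea cycle median went from -0.51 to -0.26 with library totals while the median of all genes moved by 0.246. A lower share of hepatocytes that raises all other cell types alike is argued against by the unequal medians of their markers. These ran from -0.46 in B and plasma cell to 0.34 in cholangiocyte markers (quartiles 0.04 and 0.65), with -0.05 in endothelial ones (-0.12 and 0.05). Red blood cell markers stood apart at 1.16 (0.92 and 1.30). A rise of only some cell types would also lower the share of hepatocytes, and these medians cannot exclude that. Libraries rich in ribosomal-like RNA are argued against by 35 catabolism genes called lower without the 4 of them. More blood in the tissue stays open as untested, and a response of hepatocytes to the diet may underlie the fall, as a hypothesis found and tested on the same data.

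Single libraries stood far from the other 5 of their group, by a gap that chance gives in about 1 in 20 groups of normally distributed values. CPM and shares were not put on a log scale and can be skewed, so the chance counts below may be too low. Among library measures 12 of 48 groups had such a library, where chance gives 2.4. Among the genes always named the count was 15 of 134, where chance gives 6.7, and among other named genes 144 of 1108, where chance gives 55.4.

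The share of ribosomal-like RNA was 34.9% in C57BL/6J male Control replicate 6, 9.66% in C57BL/6J male Medium Protein replicate 6 and 10.0% in DBA/2J male Control replicate 4. It was 2.53% in C57BL/6J male Low Protein replicate 2, 4.29% in C57BL/6J female Low Protein replicate 6, 2.27% in DBA/2J male Low Protein replicate 2 and 1.98% in DBA/2J female Low Protein replicate 3. In C57BL/6J female Medium Protein replicate 1 and DBA/2J female Control replicate 5 it was 0.162% and 0.0564%. The median over all libraries was 0.0207%. C57BL/6J male Control replicate 1, at 12.6%, was the 4th library above 5%, so that 2 of the 6 libraries of that group were rich in such RNA. Mitochondrial RNA took 28.0% in C57BL/6J male Low Protein replicate 1 and 17.8% in DBA/2J male Control replicate 4. The TMM factor of C57BL/6J male Control replicate 6 was 0.618.

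C57BL/6J female Control replicate 1 stood apart in 11 of the other named genes. Among the genes always named it stood apart in Asns at 7.43 CPM and Gpnmb at 8.54 CPM. Fgf21 reached 53.5 CPM in DBA/2J male Medium Protein replicate 2, and Igf1 was 354 CPM in C57BL/6J female Medium Protein replicate 5. Igfbp1 was 69.9 CPM in C57BL/6J male Control replicate 1, 154 CPM in DBA/2J female Control replicate 2 and 77.7 CPM in DBA/2J female Low Protein replicate 6. Cyp7a1 was 416 CPM in C57BL/6J male Control replicate 2 and Eif2s3y 17.7 CPM in C57BL/6J male Control replicate 3. Nnt was 33.9 CPM in DBA/2J female Medium Protein replicate 5 and Glo1 332 CPM in DBA/2J female Control replicate 4. Hc was 1287 CPM in C57BL/6J male Control replicate 4, 1156 CPM in C57BL/6J male Low Protein replicate 3, 1042 CPM in C57BL/6J female Low Protein replicate 1 and 335 CPM in DBA/2J male Low Protein replicate 5.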

How the results depend on the processing

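Removals of single libraries and of the 4 libraries rich in ribosomal-like RNA were chosen after seeing the data. Across the alternatives for all libraries, the counts for Low Protein against Control ran from 395 to 5652 in C57BL/6J males, 38 to 884 in C57BL/6J females, 0 to 43 in DBA/2J males and 13 to 274 in DBA/2J females. With RLE factors, and without the 10 most abundant genes, 0 of 22 counts moved by over 1.5 times. Of 174 pairs of a named gene and a comparison, 104 were called under every setting run, 70 were lost at least once and 4 changed sign. Lost were 40 of 174 with limma-voom, 45 of 174 against a fold of 1.2 and 40 of 163 in a fit of the compared groups only. The causes of the moves below were not tested, beyond that a stricter null, fewer animals or more genes tested changes the test itself. Depth limits genes with few counts. The filter left out genes low in all groups but kept some with few counts in the groups compared. Examples in DBA/2J females are Olfr1033, with 0 counts on Control, and Snhg11, with 23 counts on Low Protein.

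With library totals, Low Protein against Control gave 5652 genes in C57BL/6J males, 295 in C57BL/6J females, 69 in DBA/2J females and 2419 for the mean effect. Low against Medium Protein then gave 3005 and 213 genes in C57BL/6J males and females and 3 in DBA/2J females. The effect differed by sex in C57BL/6J for 2611 genes and by strain in males for 995, and sex on Control gave 8941 genes in C57BL/6J and 7288 in DBA/2J. With no filter the counts were 1258, 337 and 102 for Low Protein against Control in C57BL/6J males, C57BL/6J females and DBA/2J females, 993 for the mean, 44 for Medium Protein in C57BL/6J males, 221 and 5 for Low against Medium Protein in C57BL/6J and DBA/2J females, 421 by sex in C57BL/6J and 264 by strain in males.

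With a fold of 1.2 as the null, Low Protein against Control gave 395, 38, 4 and 13 genes in C57BL/6J males, C57BL/6J females, DBA/2J males and DBA/2J females, and 60 for the mean. Medium Protein gave 10 in C57BL/6J males, and Low against Medium Protein 269, 54 and 0 in C57BL/6J males, C57BL/6J females and DBA/2J females. By sex in C57BL/6J 72 genes differed, by strain 90 in males and 7 in females. Sex gave 1298 genes in C57BL/6J and 1170 in DBA/2J, and strain 3131 in males and 2928 in females. In a fit of the compared groups only, Low Protein against Control gave 87, 0 and 75 genes in C57BL/6J females, DBA/2J males and DBA/2J females. Medium Protein gave 0 each in C57BL/6J males, DBA/2J males and DBA/2J females, where the fit of all libraries gave 81, 1 and 1. Low against Medium Protein gave 465, 101 and 2 in C57BL/6J males, C57BL/6J females and DBA/2J females, and the effect differed by sex in C57BL/6J for 410 genes and by strain in females for 6.

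DESeq2 called 43 genes in DBA/2J males and 274 in DBA/2J females for Low Protein against Control. For Medium Protein DESeq2 called 153, 10, 5 and 9 in C57BL/6J males, C57BL/6J females, DBA/2J males and DBA/2J females, and 7 for the mean. For Low against Medium Protein it called 7 in DBA/2J males and 57 in DBA/2J females, by sex in DBA/2J 13 and by strain in females 123. With limma-voom, Medium Protein gave 41, 0 and 0 genes in C57BL/6J males, DBA/2J males and DBA/2J females, and Low against Medium Protein 24 in DBA/2J females. With a filter of 1 CPM in 6 libraries, and with the letter as a covariate, Medium Protein gave 0 genes in DBA/2J females. With 1 animal of each pair that shares a number, counts were 341 for Low Protein in C57BL/6J females, 17 for Medium Protein in C57BL/6J males, 407 by sex in C57BL/6J, 292 and 37 by strain in males and females and 2656 for sex in C57BL/6J. Overlap of calls at an adjusted p below 0.01 was 40 genes, against 131. The gene list tests gave 256 calls with the preset correlation, 16 with an estimated correlation and 122 with fry.

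Without single libraries, counts ran from 81 to 96 for Low Protein in DBA/2J females (158 with all), from 48 to 92 for Medium Protein in C57BL/6J males (81), and from 18 to 83 for the strain difference in females (18). Low Protein gave 9 genes in DBA/2J males without Control replicate 4, and also without the 4 libraries rich in ribosomal-like RNA. Medium Protein then gave 0 in DBA/2J males, and it gave 0 in DBA/2J females without Control replicate 2 or Medium Protein replicate 6. Low against Medium Protein gave 3 in DBA/2J females without Low Protein replicate 3 or Medium Protein replicate 6. Changes of sign were in C57BL/6J. With library totals Igf1, which did not pass, was 0.08 in males on Low Protein. Without single libraries, Orm2 in females ran from -1.06 (without Low Protein replicate 1) to 4.16 and Cxcl13 from -0.24 (without the same library) to 2.51, and Orm2 for Low against Medium Protein was -0.03 without it. Igdcc4 for Medium Protein in males ran from -0.11 (without Medium Protein replicate 2) to 4.36. The sex difference of the Asns response to Low Protein ran from -0.19 (without C57BL/6J female Control replicate 1) to 2.84 (without C57BL/6J female Low Protein replicate 1). No paired analysis was possible for diet, because the diet groups of a strain and sex shared 0 animal numbers. On Control, the sexes of C57BL/6J shared 2 numbers, as did males of the strains, and no fit with the number as a block was run there.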

Other observations

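On Control, several cell-type and metabolic lists beyond the sex-biased genes held genes called between the sexes of C57BL/6J. None of the lists below passed with an estimated correlation. Of 21 macrophage markers 7 were lower in males, with Vsig4 at -0.97 (adjusted p = 0.000248, lower in 6 of 6 libraries), and of 22 collagen and matrix markers 9 were lower (adjusted p = 0.506 for each list with an estimated correlation). Of 27 bile acid genes 11 were higher and 3 lower in males (adjusted p = 0.0735 with an estimated correlation), but with library totals 3 were higher and 5 lower, and the median turned from 0.28 to -0.05. With library totals 21 macrophage and 19 collagen and matrix markers were lower. Psat1 of serine synthesis answered Low Protein differently by sex in C57BL/6J (4.09, adjusted p = 0.000999, and 2.67, 0.0201 without C57BL/6J female Control replicate 1) and by strain in males (-4.29, 0.000914). Its list of serine and one-carbon genes had adjusted p = 0.0764 and 0.0541 with an estimated correlation.

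The counts below are from fits of the compared groups only, with splits of the same libraries. For Low Protein against Control, C57BL/6J males gave 1641 genes, as did 1 of 100 splits with the real one included, and the highest other gave 98. C57BL/6J females gave 87 (1 of 100, highest other 3) and DBA/2J females 75 (1 of 100, highest other 0). For Low against Medium Protein the counts were 465 in C57BL/6J males (1 of 100, highest other 1) and 101 in C57BL/6J females (1 of 100, 6). The mean Low Protein effect gave 1422 (1 of 50, 1). Differences by sex in C57BL/6J gave 410 (1 of 100, 15), by strain in males 622 (1 of 100, 2) and by strain in females 6 (1 of 100, 1). Sex gave 2832 in C57BL/6J (1 of 100, 2) and 3464 in DBA/2J (1 of 100, 56), and strain 5667 in males (1 of 100, 1) and 4261 in females (1 of 100, 517). Chance is argued against for the comparisons of diets, sexes and strains, though 1 of 100 or 1 of 50 is the lowest share such splits can give. For the differences of the diet effect by sex or strain, diets were exchanged within each strain and sex, which removes any diet effect. Those splits therefore cannot exclude chance for the difference itself. For Low against Medium Protein in DBA/2J females 2 genes were called, as many or more in 4 of 100 splits and 45 in the highest other, so that little rests on the 2 genes.

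Where the real split gave 0 genes in this fit, every split was as large by necessity, so the splits say nothing about chance there, nor about the genes that the fit of all libraries called. This was so for Low Protein in DBA/2J males (100 of 100, highest other 346) and for Medium Protein in C57BL/6J males (100 of 100, 11), C57BL/6J females (100 of 100, 233), DBA/2J males (100 of 100, 14), DBA/2J females (100 of 100, 16) and the mean (50 of 50, 3). It was also so for Low against Medium Protein in DBA/2J males (100 of 100, 2) and for the sex difference in DBA/2J (100 of 100, 47). Splits that call many genes, such as 346, 233 and 45, may point to a structure of the samples, such as outlying libraries, which was not tested, while the median of the other splits was 0 genes in these comparisons.

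Animals that share a number within a group were more alike than others on average, though not in each pair. Over 6 such pairs the mean correlation of residuals was -0.022, against -0.207 for the other pairs of the same groups (exact one-sided permutation p = 0.00659, 11390625 combinations, 11821 genes). The pairs ran from -0.3 to 0.3, 5 of 6 lay above the mean of the other pairs of their group and 2 above the highest of these. What the numbers stand for is not given in the sources used here.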
